A study of Homo sapiens with 14 samples.

How the data were processed

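The series profiled circular RNAs (circRNAs), closed RNA loops formed when a downstream splice donor joins an upstream acceptor, in HepG2, a human liver cancer cell line. Per the labels, total RNA came from 7 sources with 2 samples each, which makes 14 samples: whole cells, nucleus, cytoplasm, ribosome, cytosol, mitochondria and exosomes. Ribosomal RNA was removed with Ribo-Zero Gold from all samples except the exosomal ones, and strand-specific libraries were made, per the labels' protocols. The labels do not say whether the 2 samples of a fraction came from separate cultures. The p-values of tests between fractions therefore rest on a spread between such samples, shared over the fractions, that may be technical.

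The deposited tables hold whole-number counts of back-splice junction reads per circRNA and library, listed separately for 2 callers headed Ciri and CIRC, per the file headers. The deposited tables also give RPTM values, read here as reads per 10000000 reads of a library, for each caller and as an average. Each caller's RPTM was an exact linear function of its 2 read counts, so it implied a library total for each sample, and the average was the mean over the callers with an entry. What those totals count is not stated in the sources used here. Coordinates are on hg38, per the submitters' processing notes, and versions of the aligner and the callers were not given in the sources used here. Checked on the tables, a caller's entry was present only where both replicates had at least 1 read. A circRNA absent from a table is therefore called unlisted, which is not a measured 0. The average values carried up to 10 decimals in the cell, nucleus and cytoplasm tables and 15 in the ribosome, cytosol and exosome tables, so the tables appear to have been written in 2 groups. Of the 3 comparisons only exosome against cell crosses these groups, and so do the shares of ribosomal and cytosolic entries found in the cytoplasm table. The tables give no strand, gene name or exon, and they cover 6 fractions. The 2 mitochondrial samples were not analysed here.

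Tables were joined on identical chromosome, start and end. Reads of a circRNA in a library were the mean of the callers with an entry, rounded to a whole number. Levels are in RPTM, on the implied library totals, and given as mean ± SD of the 2 libraries (n = 2) throughout. Host genes were assigned where both ends lay inside the span of 1 gene in the RefSeq table of assembly GRCh38.p14, protein-coding genes first. Of 11227 circRNAs, 10950 had a host by this rule, and 178 lay in more than 1 equally ranked gene. Strand was not used, so a host can be an antisense neighbour. Exonic and intronic classes and spliced length were not analysed here, and length is the genomic span between the ends.

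Counts were tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3, in 1 fit over the 12 libraries with 1 coefficient per fraction. The 3 comparisons were nucleus against cytoplasm, ribosome against cytosol and exosome against cell. This test, the named circRNAs, the gene lists and most alternatives were chosen before the data were examined. The set of circRNAs tested was chosen after a first fit over all entries: the 4834 with an entry by both callers in at least 1 table, of which 951 passed edgeR's filterByExpr with a minimum count of 10. TMM fold changes compare a circRNA with the other circRNAs of its library, not with all RNA. They are not plain ratios of shares of circRNA reads. The TMM factors were 1.93 and 2.25 in the exosomal libraries and 0.77 to 0.925 elsewhere, so exosomal fold changes lie below changes in share. Because an unlisted circRNA entered as 0, each comparison also gives the calls that passed in the same direction in 4 fits: with TMM and with total circRNA reads as the scale, each with unlisted circRNAs at 0 and at 1 read. These are called calls kept in the 4 fits, and the rule was chosen after the data were examined. No fold change is given against a fraction that does not list the circRNA. The ± of a log2 fold change is an approximate standard error (SE). It is the absolute fold change divided by the square root of the F statistic of its test.

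Named circRNAs were, per comparison, the 12 with the largest absolute log2 fold change in each direction among those that passed and whose libraries did not overlap, at most 1 per host gene. The 10 most abundant per fraction and the most abundant members of 12 host gene lists were also named. Because most of the first group were unlisted in 1 fraction, the same rule among circRNAs listed in both tables was added after the data were examined. Abundant circRNAs are those of the tested set, and abundant single-caller entries are described separately. Gene lists were tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry in limma 3.58.1. Spans were compared by two-sided permutation tests over circRNAs with 100000 resamples, and shares of entries by two-sided Fisher's exact tests, in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3. Shares of listed circRNAs have 95% Wilson intervals, which cover counting error only. Plots were drawn with matplotlib 3.10.9.

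Alternatives were RLE factors, total circRNA reads, the implied library totals, no filter and a stricter one, DESeq2 1.42.0, fits of only the compared fractions, a replicate block, each replicate left out, each caller alone, entries of either caller, reads summed per host gene, unlisted circRNAs at 1 read, and cytosol in place of cell. The fit was tested on simulated data drawn from the real means with the same listing rule. All libraries were given 1 common spread between replicates, a coefficient of variation of 17.6%. In 1 draw per comparison, 200 circRNAs were changed by known amounts, and shares are of those that passed the filter. In all, 756, 840 and 802 simulated circRNAs were tested, unchanged ones included. Of those 3 log2 units higher, 97.2% of 36 were recovered in the nucleus, 100% of 36 in the ribosome and 48.3% of 29 in the exosome. Of those 1 unit higher, 15.8% of 19, 16.7% of 18 and 0% of 13 were recovered. For those 3 units lower the shares were 83.3% of 12, 90% of 20 and 20% of 10. Unchanged circRNAs made up 44.9% of calls for nucleus, 23.6% for ribosome and 74.2% for exosome, and 10%, 9.89% and 0% of calls kept in the 4 fits. The 4 fits kept 94.4%, 100% and 27.6% of those 3 units higher, but 58.3%, 80% and 0% of those 3 units lower. The replicates of a fraction were also compared by a chi-square test per circRNA. The ratio of chi-square to its degrees of freedom was 1.11 in the nucleus (p = 0.103), the 1 pair within sampling noise, and 1.24 to 1.84 in the other fractions. The exosomal libraries had the weakest correlation, a Pearson r of log2 values of 0.255 over 88 circRNAs, against 0.662 to 0.767 in the other fractions. The nuclear libraries held different values and were kept as 2 samples.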

Results

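CircRNA junction reads were collected from 6 fractions of HepG2 cells, with 2 libraries each. The 12 libraries held between 2301 and 72415 circRNA reads. The cell libraries had 52855 and 41663, the nuclear ones 7727 and 7235, the cytoplasmic ones 72415 and 59323, the ribosomal ones 27431 and 19649, the cytosolic ones 60701 and 59472, and the exosomal ones 2304 and 2301. The library totals implied by the deposited values ran from 65.6 M to 104 M reads. Nuclear and exosomal values therefore rest on far fewer circRNA reads than the others.

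CircRNA reads made up the largest part of the cytoplasmic libraries, at 7295 ± 407 RPTM (reads per 10000000 library reads, mean ± SD, n = 2), followed by cytosol at 6071 ± 508 and whole cells at 5524 ± 166. The ribosome fraction held 2805 ± 41.3, the nucleus 904 ± 20.9 and the exosomes 290 ± 86.1. The cytoplasmic level was 8.07 times the nuclear one, the cytosolic level 2.16 times the ribosomal one, and the cell level 19.0 times the exosomal one. Single entries of the caller headed Ciri alone weighed on these levels. ALB held 18.9% of cell and 17.3% of cytoplasmic circRNA reads, and FGG 14.7% of cytosolic ones. For circRNAs that both callers list in at least 1 table the ratios were 7.36, 2.16 and 17.2. In each of these pairs both libraries of 1 fraction lay above both of the other, but with 2 libraries against 2 an exact two-sided permutation test cannot go below p = 0.333. Exosomal RNA alone was not depleted of ribosomal RNA, so its level per total reads has another denominator.

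**Figure D1:**
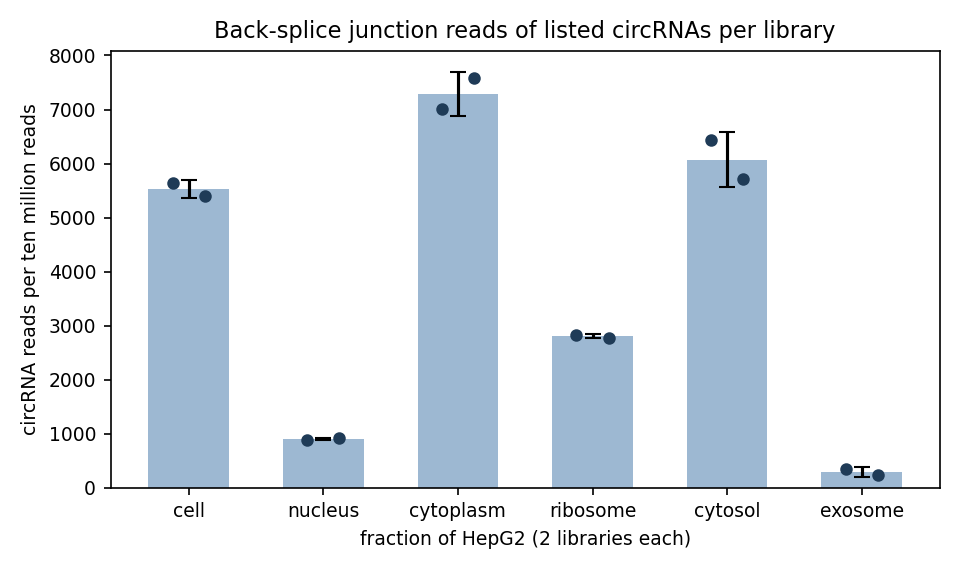
CircRNA junction reads per 10000000 reads of the library (vertical axis) in each of the 12 libraries, by fraction, with the mean of the 2 libraries. Cytoplasm lies highest with a mean of 7295, and nucleus and exosome lowest with 904 and 290.

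A few circRNAs led most fractions. The circRNA of FAT1, an atypical cadherin gene (chromosome 4, 186706563 to 186709845), was first in cell, cytoplasm and ribosome, with 92.2 ± 4.51, 108 ± 11.9 and 74.5 ± 12.6 RPTM. The circRNA of ASPH, which encodes an aspartyl hydroxylase of the endoplasmic reticulum (chromosome 8, 61680968 to 61684188), was first in the nucleus with 44.1 ± 0.508 and second in cell and cytoplasm with 67.7 ± 2.85 and 83.4 ± 1.84. In the cytosol, the circRNAs of the transcription factor gene NFATC3 (chromosome 16, 68121987 to 68126610; 45.7 ± 10.1) and of UBXN7 (chromosome 3, 196391813 to 196403019; 44.9 ± 3.09) led. In exosomes, the circRNA of the nuclear export receptor gene XPO1 (chromosome 2, 61522611 to 61533903) led with 4.07 ± 3.08. It had 41 and 19 reads, against 25 and 19 for ARHGAP12, so its lead rested on replicate 1. FAT1, ASPH, HIPK3 and CDYL circRNAs were each among the 10 most abundant of 5 fractions. The HIPK3 circRNA, from a protein kinase gene (chromosome 11, 33286413 to 33287511), missed that list only in the nucleus, where it had 1.91 ± 1.07 against 40.9 ± 3.26 in the cytosol.

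**Figure D2:**
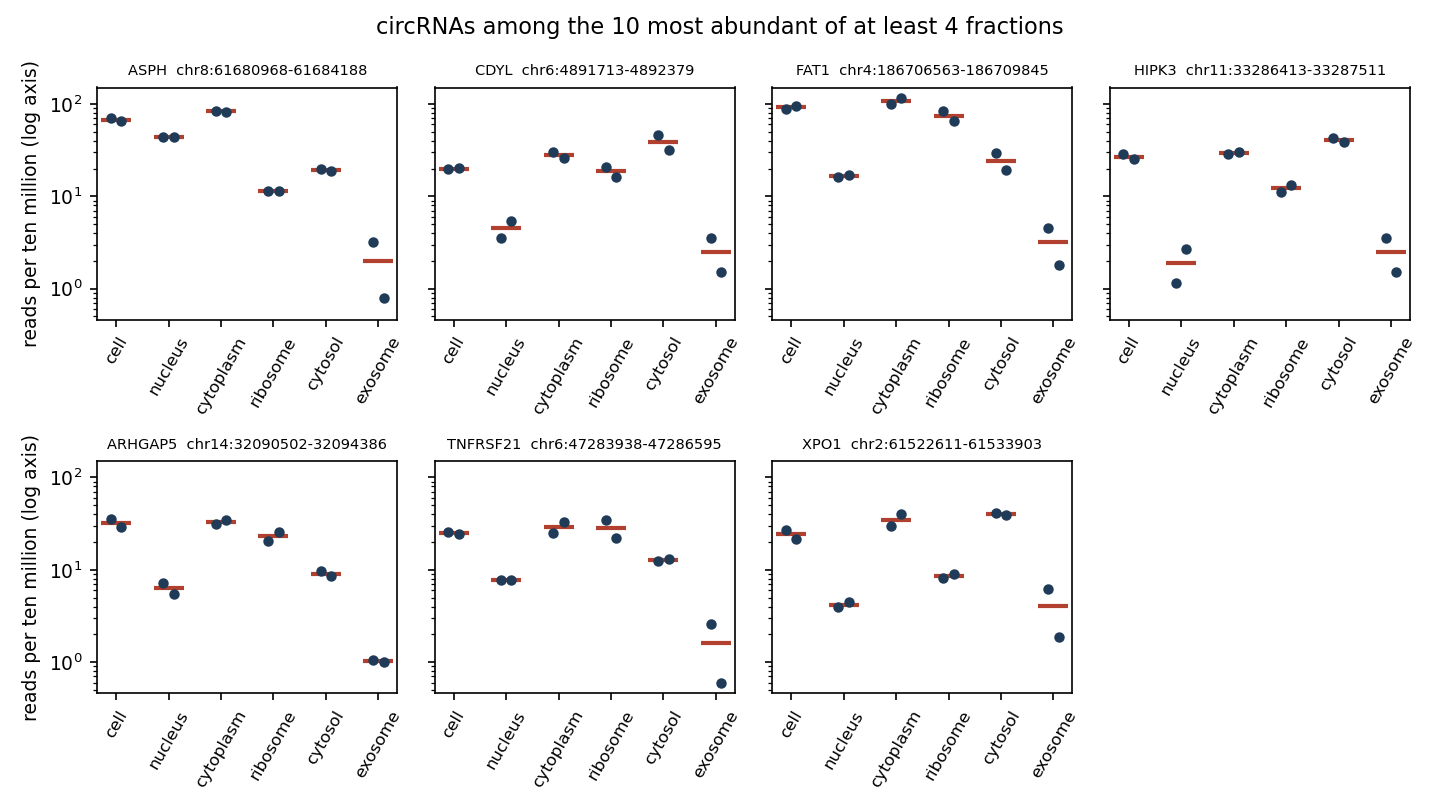
Levels of abundant circRNAs, named by host gene, in RPTM (logarithmic axis) in each library of the 6 fractions. FAT1 reaches 108 in the cytoplasm and 24.3 in the cytosol, while HIPK3 reaches 29.4 and 40.9.

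The 6 tables together listed 11227 circRNAs from 4049 host genes. They listed 5333 in cells, 1302 in the nucleus, 6968 in the cytoplasm, 2899 in the ribosome fraction, 5105 in the cytosol and 442 in exosomes. BIRC6, an inhibitor of apoptosis gene, gave 29 different circRNAs in the cytoplasm and 26 in cells. UBAP2 gave 23 in the cytosol and 13 in the ribosome fraction, MAD1L1 gave 9 in the nucleus and NFATC3 gave 5 in exosomes. These numbers depend on the number of circRNA reads: drawn down to 2301 circRNA reads per library, the fractions listed 455, 592, 436, 523, 461 and 442 on average, in the same order. Exosomal libraries were hardly drawn down, while elsewhere entries left in 1 library were dropped, so the draw did not give fully equal depths. A total of 5907 circRNAs (52.6%) were in 1 table and 183 in all 6.

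Nuclear circRNAs were mostly also cytoplasmic: 978 of 1302 (75.1%, interval 72.7 to 77.4) were in the cytoplasm table, and 92.7% of those in the tested set. That set favours shared circRNAs, because an entry by both callers in another table admits them. It held 873 nuclear circRNAs, of which both callers listed 424 in the nucleus. Of the ribosomal circRNAs, 1783 of 2899 (61.5%, 59.7 to 63.3) were in the cytosol table and 71.6% in the cytoplasm table. Of the exosomal circRNAs, 369 of 442 (83.5%, 79.7 to 86.7) were in the cell table. The genomic span of circRNAs listed in the nucleus but not the cytoplasm had a median of 2171 bases (324 circRNAs), against 6750 bases for the reverse (5990 circRNAs). That difference had p = 1e-05 in the permutation test, the smallest it can give, though over all listed circRNAs (1302 and 6968), weighted by reads, the nuclear median was 60 bases longer. Ribosome-only and cytosol-only circRNAs had medians of 7203 and 6831 bases (permutation p = 0.392), and exosome-only and cell-only ones 4646 and 6668 bases (permutation p = 0.205).

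Entries whose ends did not lie in 1 gene were 50 of 1302 (3.84%) in the nucleus and 93 of 6968 (1.33%) in the cytoplasm (odds ratio 2.95, Fisher's exact p = 1.73e-08). They were 87 of 2899 (3.0%) in the ribosome fraction and 99 of 5105 (1.94%) in the cytosol (odds ratio 1.56, Fisher's exact p = 0.00325), and 2.49% and 1.74% in exosomes and cells (Fisher's exact p = 0.261). Many circRNAs were counted in both fractions of a pair, such as 978 of the 1302 nuclear ones. The groups are therefore not independent, and these p-values are only descriptive. All entries whose ends did not lie in 1 gene came from the caller headed Ciri alone. Entries on the mitochondrial genome numbered 21 in the cytosol with 26.7 and 32.6 RPTM. There were 2 in exosomes and 1 in the ribosome fraction, and cell, nucleus and cytoplasm listed none. This split matches the 2 groups in which the tables appear to have been written, so it is not read as a difference between compartments. The caller headed CIRC listed none of them.

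Nucleus and cytoplasm are the first split of the cell in the design. The circRNA of CAMSAP1, which encodes a protein of microtubule minus ends (chromosome 9, 135881633 to 135883078), had 23.0 ± 0.150 RPTM in the nucleus and 12.6 ± 1.76 in the cytoplasm, a log2 fold change of 3.37 ± 0.27 (SE) among circRNA reads (adjusted p = 7.0e-12). The circRNA of SDF4, a calcium-binding protein gene of the Golgi (chromosome 1, 1223244 to 1223968), had 12.6 ± 2.59 and 8.13 ± 1.91 (3.10 ± 0.31, adjusted p = 3.5e-09), and that of P4HB, a protein disulfide isomerase gene (chromosome 17, 81855142 to 81855586), had 5.23 ± 1.22 and 5.65 ± 0.326 RPTM, with a higher share of circRNA reads (2.37 ± 0.30). The ASPH circRNA was lower in the nucleus per total reads, at 44.1 against 83.4, but its share of circRNA reads was higher (1.57 ± 0.24, adjusted p = 6.3e-06). In the other direction, circRNAs of GDI2, a regulator of Rab proteins (chromosome 10, 5794885 to 5800705), and GOLPH3, a Golgi protein gene (chromosome 5, 32135572 to 32143880), had log2 fold changes of −3.55 ± 0.65 and −2.19 ± 0.54. The GOLPH3 call was lost without nuclear replicate 1 (adjusted p = 0.0734) and under DESeq2.

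Several circRNAs were listed in only 1 of the 2 fractions. The GUSBP1 circRNA (chromosome 5, 21491321 to 21497196) had 34 and 37 nuclear reads and was not listed in the cytoplasm, although cell, ribosome and cytosol listed it at 3.27 ± 0.213, 4.44 ± 0.883 and 2.48 ± 0.243. AP3D1 (chromosome 19, 2137727 to 2138714), an adaptor complex gene, had 22 and 12 nuclear reads. In the cytoplasm, the circRNAs of the histone demethylase gene KDM4C (chromosome 9, 6880012 to 6893232; 101 and 100 reads), of NAB1 (chromosome 2, 190659158 to 190673152; 67 and 54) and of the apolipoprotein gene APOB (chromosome 2, 21024933 to 21026964; 63 and 23) were not listed in the nucleus, and APOB was listed in no other fraction. The APOB call was lost with a filter of at least 5 reads in at least 2 libraries (edgeR adjusted p = 0.0522).

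Of 951 circRNAs tested by edgeR, 458 differed between nucleus and cytoplasm, 142 higher and 316 lower in the nucleus. The nucleus did not list 277 of the lower ones, and 169 calls were kept in the 4 fits, 114 higher and 55 lower. The split moved with the scale: RLE factors gave 181 higher and 233 lower, and the implied library totals 24 higher and 772 lower. The balance turned in other fits: without nuclear replicate 1 there were 99 calls, 75 higher and 24 lower, and without replicate 2 143, 86 and 57. DESeq2 made 106, 64 and 42, unlisted circRNAs at 1 read left 171, 116 and 55, and circRNAs listed in both tables gave 148, 93 and 55. In 1 simulated draw the rule of the 4 fits kept decreases less well. It kept 94.4% of 36 circRNAs 3 log2 units higher in the nucleus and 58.3% of 12 that were 3 units lower.

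Among host gene groups, none of the 36 circRNAs of RNA-binding and splicing factor genes was higher in the nucleus, 18 were lower and 18 did not pass. The 2 that were kept in the 4 fits were those of RBM33 (chromosome 7, 155672867 to 155680908; −1.94 ± 0.45) and METTL3, the catalytic subunit of the RNA adenosine methyltransferase (chromosome 14, 21503173 to 21503881; −1.73 ± 0.56). That of HNRNPC (chromosome 14, 21230319 to 21234229; −1.31 ± 0.50) was not kept, and with RLE factors 2 of the 36 were higher and 12 lower. Chromatin genes had 2 higher and 13 lower of 38, of which 1 and 7 were kept, with CREBBP (chromosome 16, 3850297 to 3851009; −1.41 ± 0.49) and BAZ1A (chromosome 14, 34862044 to 34862322; −1.56 ± 0.42) among the lower. Genes known for their circRNAs had 3 higher and 20 lower of 46, of which 3 and 9 were kept, including HIPK3 (−1.47 ± 0.33), ZKSCAN1 (chromosome 7, 100023419 to 100024307; −1.33 ± 0.35) and SMARCA5 (chromosome 4, 143543509 to 143543972; −1.02 ± 0.35). Ubiquitin pathway genes had 2 and 14 of 40, kinases 2 and 12 of 31, membrane trafficking 2 and 14 of 27, cytoskeleton and motors 2 and 7 of 19, nuclear transport 4 and 4 of 13, translation 2 and 3 of 8. Hosts reported for nuclear circRNAs had 2 and 5 of 14, hepatocyte metabolism genes 0 and 3 of 6, and secreted liver proteins 1 and 1 of 4. With RLE factors nuclear transport genes had 4 higher and 2 lower, membrane trafficking 2 and 6, ubiquitin 2 and 8, and known circRNA hosts 4 and 12. With the implied library totals the calls of all 12 lists were mostly lower: RNA-binding genes had 0 higher and 33 lower, chromatin 1 and 33, known circRNA hosts 1 and 43, ubiquitin 0 and 37, kinases 1 and 29, and membrane trafficking 1 and 23. Cytoskeleton and motors had 1 and 15, nuclear transport 0 and 10, translation 0 and 7, nuclear circRNA hosts 1 and 12, hepatocyte metabolism 0 and 5, and secreted liver proteins 0 and 3.

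Adjusted over the list alone, the ubiquitin group had 1 higher and 11 lower, nuclear circRNA hosts 2 and 6, and hepatocyte metabolism 1 and 3, and the other lists kept their counts. No list stood apart from the other circRNAs by camera, with a smallest adjusted p = 0.255, and a smallest adjusted p = 0.608 with an estimated correlation. At unadjusted p under 0.05, camera gave 2 lists, RNA-binding and chromatin genes. With an estimated correlation their unadjusted camera p was 0.138 and 0.224. The fry test asks whether members of a list move 1 way on balance, without setting them against other circRNAs. It passed downward for 7 lists, with adjusted p = 3.6e-04 for ubiquitin and 0.00246 for RNA-binding genes, while the median log2 fold change of all 951 was itself −0.77, or −0.37 with RLE factors and −3.18 with the implied library totals. Those medians include circRNAs not listed in the nucleus, entered as 0, and for the 528 listed in both tables the median was 0.36. Medians were negative where camera pointed up for nuclear transport, translation and cytoskeleton genes, and secreted liver proteins had a median of 0.44 and a mean of −1.09.

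Ribosome and cytosol divide the cytoplasm further. The FAT1 circRNA had 74.5 ± 12.6 RPTM in the ribosome fraction and 24.3 ± 6.81 in the cytosol, a log2 fold change of 2.53 ± 0.24 (edgeR adjusted p = 1.4e-09). The circRNAs of ARHGAP5 (chromosome 14, 32090502 to 32094386; 23.2 ± 3.74 and 9.09 ± 0.773, 2.24 ± 0.26), and TNFRSF21, a death receptor gene (chromosome 6, 47283938 to 47286595; 28.7 ± 8.98 and 12.7 ± 0.471, 2.04 ± 0.27), were also higher in the ribosome fraction. So were those of FAM169A (chromosome 5, 74834426 to 74841679; 3.11 ± 0.30) and CAMSAP1 (3.05 ± 0.32). In the other direction, the circRNA of the casein kinase gene CSNK1G3 (chromosome 5, 123545417 to 123557564) had 1.93 ± 0.335 in the ribosome fraction and 25.9 ± 5.43 in the cytosol (−2.82 ± 0.32, adjusted p = 1.8e-08), and PCMTD1 (chromosome 8, 51860845 to 51861246) had 0.818 ± 0.158 and 16.0 ± 1.67 (−3.39 ± 0.38).

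The circRNA of KIF5B, a kinesin heavy chain gene (chromosome 10, 32028428 to 32037607), had 36 and 26 ribosomal reads and was not listed in the cytosol. That of GPBP1L1 (chromosome 1, 45640210 to 45642499) had 87 and 85 cytosolic reads, and that of the chaperonin subunit gene CCT2 (chromosome 12, 69589485 to 69592159) 57 and 85, and neither was listed in the ribosome fraction. The most abundant cytosolic circRNAs of UBXN7 (−0.86 ± 0.28) and HIPK3 (−0.84 ± 0.26) were lower in the ribosome fraction, whereas CDYL (chromosome 6, 4891713 to 4892379) had −0.14 ± 0.24 and did not pass.

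Of 951 circRNAs, 501 differed, 253 higher and 248 lower in the ribosome fraction, and 422 were kept in the 4 fits, 223 higher and 199 lower. The implied library totals, which moved the median log2 fold change from 0 to −0.71, gave 133 higher and 382 lower. Without a filter 601 were higher and 1263 lower of 4834, and with at least 5 reads in at least 2 libraries 294 and 956 of 2656. DESeq2 called 262, and circRNAs listed in both tables gave 304. No single replicate left out moved the count by 1.5 times.

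Of 13 circRNAs of nuclear transport genes, 2 were higher and 6 lower in the ribosome fraction, and 5 did not pass. Those lower included the importin gene KPNA5 (chromosome 6, 116689320 to 116692392; 1.74 ± 0.130 and 19.5 ± 4.56, −2.58 ± 0.31), XPO1 (−1.34 ± 0.26) and the nucleoporin gene NUP54 (chromosome 4, 76134175 to 76144473; −1.83 ± 0.43). Membrane trafficking genes had 4 higher and 9 lower of 27, with VAPA, an anchor of the endoplasmic reticulum (chromosome 18, 9931810 to 9937066), at −2.58 ± 0.28. Kinase genes had 3 and 10 of 31, and RNA-binding genes 6 and 12 of 36, with the splicing factor RBM39 (chromosome 20, 35729312 to 35732135) at −2.13 ± 0.30 and the helicase DDX21 (chromosome 10, 68959806 to 68960249) at −2.66 ± 0.39. Cytoskeleton and motor genes had 8 higher and 3 lower of 19, among them CAMSAP1, KIF5B and CORO1C (chromosome 12, 108652272 to 108654410; 1.22 ± 0.31), but 6 and 6 with the implied library totals. Translation genes had 3 and 1 of 8, which turned to 1 and 3 with those totals, known circRNA hosts 11 and 16 of 46, chromatin 9 and 11 of 38, ubiquitin 8 and 11 of 40, nuclear circRNA hosts 4 and 7 of 14, hepatocyte metabolism 1 and 2 of 6, and secreted liver proteins 1 and 0 of 4. With the implied library totals known circRNA hosts had 4 higher and 20 lower, chromatin genes 5 and 18, ubiquitin 4 and 19, RNA-binding genes 2 and 20, kinases 1 and 17, and membrane trafficking 3 and 15. Nuclear transport genes then had 1 and 7, nuclear circRNA hosts 2 and 8, hepatocyte metabolism 0 and 2, and secreted liver proteins 1 and 0.

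Adjusted over the list alone, nuclear transport had 2 higher and 7 lower, nuclear circRNA hosts 5 and 7, and hepatocyte metabolism 2 and 2, with the other counts as above. By fry, kinases and membrane trafficking (both adjusted p = 1.2e-04) and nuclear transport (6.2e-04) moved down, and cytoskeleton and motors moved up (4.4e-04). No list passed camera (smallest adjusted p = 0.384, and adjusted p = 0.467 with an estimated correlation), and none passed at unadjusted p under 0.05, so none was shown to differ from the other circRNAs. RNA-binding genes (0.0254) and nuclear circRNA hosts (0.0254) also moved down by fry. Hepatocyte metabolism genes had a median of 0.84 and a mean of −1.37, and chromatin genes −0.01 and 0.08.

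Exosomes were set against the cells that released them. The circRNAs of ASPH (2.0 ± 1.7 RPTM in exosomes and 67.7 ± 2.85 in cells), FAT1 (3.18 ± 1.96 and 92.2 ± 4.51) and ARHGAP5 (1.03 ± 0.0494 and 32.3 ± 4.24) were lower in exosomes on the TMM scale. Their log2 fold changes were −2.77 ± 0.32, −2.49 ± 0.29 and −2.45 ± 0.36 (edgeR adjusted p = 2.2e-07, 2.2e-07 and 2.8e-05). Shares of reads differed less: in the tested set ASPH made up 0.978% of reads in exosomes and 2.03% in cells, and FAT1 1.62% and 2.75%. That of ECPAS, a proteasome adaptor gene (chromosome 9, 111386377 to 111391824), had 107 and 47 cell reads and was not listed in exosomes. In contrast, the circRNAs of the lysyl hydroxylase gene PLOD2 (chromosome 3, 146121112 to 146124229; 18 and 15 exosomal reads, 26 and 20 in cells; 2.12 ± 0.882 RPTM against 2.69 ± 0.127) and of BPTF, a chromatin remodeling gene (chromosome 17, 67945409 to 67975958; 7 and 5 reads against 4 and 5; 0.783 ± 0.402 against 0.538 ± 0.157), were higher in exosomes on the TMM scale, by 2.07 ± 0.39 and 2.92 ± 0.68 (adjusted p = 5.4e-04 and 0.00277). The BPTF call was lost without exosomal replicate 1 (adjusted p = 0.0615). XPO1 (−0.25 ± 0.30) and MAN1A2 (chromosome 1, 117402186 to 117420649; 0.38 ± 0.32) did not pass.

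Of 951 circRNAs, 440 differed, 39 higher and 401 lower in exosomes, and exosomes did not list 373 of the lower ones. Only 17 calls were kept in the 4 fits: the 4 lower ones above, and 13 higher. In simulated data that rule kept 27.6% of 29 circRNAs 3 log2 units higher in exosomes. It kept 0% of 15, 14 and 10 that were 1, 2 and 3 units lower, so the balance of kept calls is not read as a direction. The other higher ones, named after their values were seen, were ARID1A, COP1, EXOC6, MAML2, ZNF652, CCNYL1, FNDC3B, HMGCS1, FCHO2, IBTK and SEC63, each with 2 to 17 reads per exosomal library. COP1, EXOC6 and FCHO2 were not listed in cells. RLE factors gave 47 higher and 190 lower, and total circRNA reads 78 higher and 48 lower, which turns the balance. The implied library totals gave 11 higher and 841 lower. Without exosomal replicate 1 there were 41 calls, 11 higher and 30 lower, and without replicate 2 100, 15 and 85. DESeq2 made 63, 5 and 58, unlisted circRNAs at 1 read left 49, 13 and 36, and circRNAs listed in both tables gave 28, 12 and 16. Against cytosol, whose table is formatted like that of the exosomes, 421 differed, 52 higher and 369 lower.

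Translation genes had no exosomal call among 8 circRNAs (8 not passed), but 0 higher and 8 lower with the implied library totals. Cytoskeleton and motor genes had none higher and 11 lower of 19, including CAMSAP1 (−2.0 ± 0.39 on the TMM scale). The HIPK3 circRNA had −1.04 ± 0.32 on the TMM scale, but its share of reads of the tested set was 1.28% in exosomes and 0.808% in cells. Neither the CAMSAP1 nor the HIPK3 call was kept in the 4 fits. Known circRNA hosts had 4 higher and 14 lower of 46, chromatin genes 4 and 14 of 38, RNA-binding genes 1 and 16 of 36, ubiquitin 2 and 17 of 40, kinases 1 and 11 of 31, nuclear transport 0 and 3 of 13, and membrane trafficking 3 and 10 of 27. Nuclear circRNA hosts had 1 and 2 of 14, hepatocyte metabolism 1 and 3 of 6, and secreted liver proteins 0 and 2 of 4. Adjusted over the list alone, kinases had 1 and 9, known hosts 4 and 13, and nuclear circRNA hosts 1 and 1, with the other counts as above. With total circRNA reads as the scale these balances were lost or turned: known hosts had 8 higher and 3 lower, chromatin genes 6 and 3, ubiquitin 4 and 2, RNA-binding genes 2 and 1, kinases 3 and 2, membrane trafficking 3 and 0, nuclear transport 1 and 1, and cytoskeleton and motors 0 and 1. With the implied library totals nearly all calls were lower: known hosts had 1 higher and 40 lower, chromatin genes 0 and 29, ubiquitin 1 and 33, RNA-binding genes 1 and 32, kinases 0 and 29, and membrane trafficking 1 and 22. Nuclear transport then had 0 and 12, cytoskeleton and motors 0 and 17, nuclear circRNA hosts 0 and 12, hepatocyte metabolism 0 and 5, and secreted liver proteins 0 and 3. By fry, 10 lists moved down, ubiquitin with the smallest adjusted p = 1.3e-04. Simulated unchanged data under the same listing rule had a median log2 fold change of −5.47. The fry test therefore cannot tell a decrease in exosomes from the listing rule. No list passed camera (smallest adjusted p = 0.422, and adjusted p = 0.635 with an estimated correlation), and none at unadjusted p under 0.05. The median of all 951 was −5.17, as most were not listed in exosomes, and −0.03 for the 330 listed in both tables, and camera placed all lists except cytoskeleton and motors above the others although their medians were negative.

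**Figure D3:**
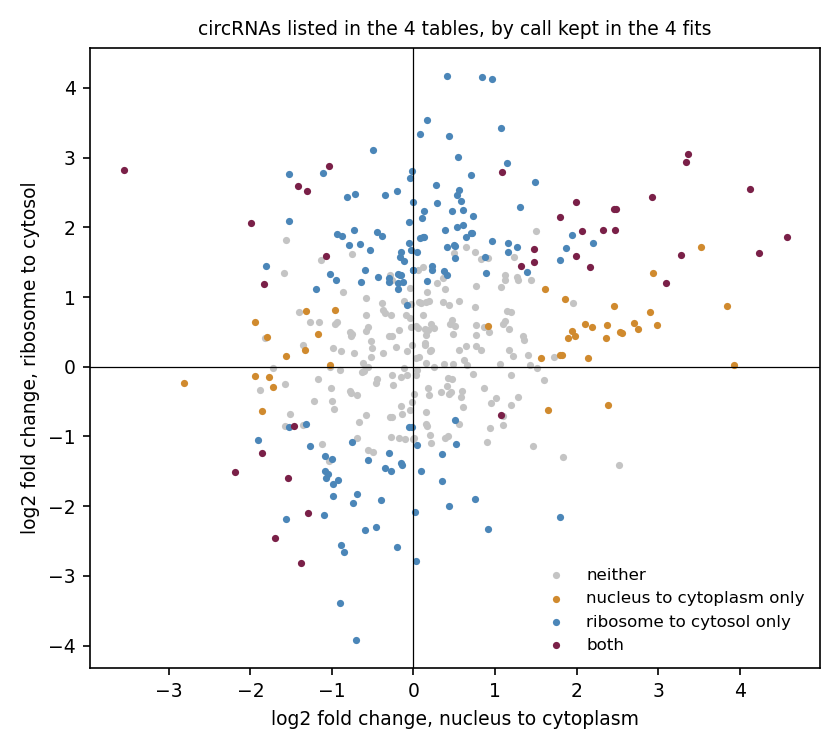
Log2 fold change of nucleus against cytoplasm (horizontal axis) and of ribosome against cytosol (vertical axis), 1 point per circRNA, for the 417 tested circRNAs listed in all 4 tables, coloured by whether a call was kept in neither, either or both comparisons. CAMSAP1 lies high on both, at 3.37 and 3.05.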

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

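The fits with entries of either caller, with each caller alone, with the implied library totals, with unlisted circRNAs at 1 read and with cytosol in place of cell were chosen after the data were examined. So were all results limited to circRNAs that both callers list in at least 1 table. The nuclear and exosomal libraries held the fewest circRNA reads: 277 of the lower calls in the nucleus and 373 in exosomes are of circRNAs not listed there. Of the values of named circRNAs and of other values that answer no comparison, 2010 kept their direction and side of the threshold, 174 lost the call, 23 moved and 6 lost the call and turned in sign. Of the values that answer a comparison, 176 were the same, 48 moved and 2 reversed. The 176 include all host gene lists, which passed camera in no fit. They also include settings that the listing rule fixed in advance, at least 2 reads and a listing in both replicates. The tally is therefore not a measure of how stable the results are. No list passed camera with an estimated correlation, the replicate block or 1 value per host gene either. Where no cause is named, the cause was not tested.

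For nucleus against cytoplasm (458 calls), no low-count filter gave 821, DESeq2 106, only the libraries of the compared fractions 225, 148 for circRNAs listed in both tables, entries of either caller 790, the implied library totals 796 and unlisted circRNAs at 1 read 171. For ribosome against cytosol (501), no filter gave 1864, at least 5 reads in at least 2 libraries 1250, DESeq2 262 and the limit to circRNAs listed in both gave 304. For exosome against cell (440), RLE factors gave 237, total circRNA reads 126, at least 5 reads in at least 2 libraries 176, DESeq2 63, only the compared fractions 88, 28 for circRNAs listed in both tables, the implied library totals 852 and unlisted circRNAs at 1 read 49. Filters and the limit to listed circRNAs change how many were tested. With each replicate left out in turn, the counts ran from 99 to 410, from 348 to 466 and from 41 to 393. The lowest came without nuclear replicate 1 (99) or 2 (143) and exosomal replicate 1 (41) or 2 (100). The lone sample was then assumed to vary like the other groups.

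Under the implied library totals, the exosome calls of CCNYL1 (−0.12), SH3GLB1 (−0.17), LMO7 (−0.19), EPS15 (−0.38), TBCD (−0.34) and ZNF652 (−0.35) were lost and their values turned in sign (adjusted p from 0.589 to 0.886), as that scale lowers exosomal values. Of 137 named calls, DESeq2 lost 51, unlisted circRNAs at 1 read 18 and the implied library totals 17, those 6 included. The filter of at least 5 reads in at least 2 libraries lost 14 and kept 111. Without exosomal replicate 1 or 2, 16 and 15 exosome calls were lost and 25 and 26 kept, and without nuclear replicate 1 or 2, 9 and 8 nuclear calls were lost and 39 and 40 kept. Replicate numbers shared between fractions gave correlations of deviations from −0.114 to 0.20, with 1 pair of libraries per fraction. These values cannot show whether samples with the same number came from 1 culture, which the labels do not say. With a replicate block the counts were 466, 499 and 449, and no named call was lost.

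Drawn down to 2301 circRNA reads, cell listed 455, nucleus 592, cytoplasm 436, ribosome 523 and cytosol 461. Circular RNAs of the tested set numbered 3198 in cell, 3840 in cytoplasm, 1892 in ribosome and 3011 in cytosol, and those with at least 5 reads 817 in nucleus and 281 in exosome. Nuclear circRNAs in the cytoplasm table were 80.0% with at least 5 reads, 87.2% by host gene and 92.7% in the tested set. Ribosomal ones in the cytosol table were 68.9%, 79.3% and 75.7%, and exosomal ones also in cells 89.3%, 94.2% and 92.0%. The definition of the tested set can itself raise its shares, as listing in another table helps an entry to qualify. Of its 362 exosomal circRNAs, both callers listed 142 in exosomes. Over all listed circRNAs, weighted by reads, so that both the set and the weighting changed, median spans differed by 60 bases for nucleus less cytoplasm, a reversal, by 2220 for ribosome less cytosol and by −209 for exosome less cell. In the tested set ribosome less cytosol reversed to −523. The share of reads from entries outside 1 gene differed by 11.8, 12.2 and 2.65 percentage points. In the tested set no entry lay outside a gene, so that alternative gave no value. Another pseudocount was not run as counts were given, and genomic span, planned as an alternative, was the length used. Exonic and intronic classes were not run.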

Other observations

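The tests on scaling and on entries of 1 caller were chosen after the results were seen, and the calls kept in the 4 fits were defined after the data were examined.

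Circular RNAs of 1 host gene did not always share a distribution. RERE, a transcriptional corepressor gene, had 1 circRNA (chromosome 1, 8655973 to 8656441) with 4.98 ± 0.848 RPTM in the ribosome fraction and 2.18 ± 0.508 in the cytosol (log2 fold change 2.09 ± 0.33), and another (8541214 to 8614686) with 1.60 ± 0.662 and 8.91 ± 1.33 (−1.54 ± 0.36). GDI2 had 1 circRNA (chromosome 10, 5794885 to 5800705) higher in the ribosome fraction (2.83 ± 0.37) and another (5785142 to 5800705) lower (−1.13 ± 0.44). The 4 circRNAs of MAN1A2, a Golgi mannosidase gene, which share their start (chromosome 1, 117402186), were all lower in the ribosome fraction, from −1.60 ± 0.35 to −2.18 ± 0.34. Of the XPO1 circRNAs sharing a start, the shorter (chromosome 2, 61522611 to 61526521) had 4.0 ± 0.620 RPTM in the nucleus and 10.4 ± 3.02 in the cytoplasm, and only its share of circRNA reads was higher (1.08 ± 0.32, edgeR adjusted p = 0.00781), and the longer (61522611 to 61533903) had −0.56 ± 0.29 (adjusted p = 0.0986). Differences within a host gene were not tested, and all were named after their values were seen.

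A hypothesis written before its test was that the ribosome fraction carries circRNAs of the nuclear fraction. Across the 417 circRNAs listed in the 4 tables, the nuclear and ribosomal contrasts had Spearman rho 0.267 and Pearson r 0.259 (permutation p = 1e-05, the smallest it can give, adjusted 4e-05 over 4 correlations). These are correlations across circRNAs, which are not independent replicates. Of the 49 kept as higher in the nucleus, 21 were kept as higher in the ribosome fraction and 1 as lower. Of the 341 with no kept nuclear call these were 95 and 45, and of the 27 kept as lower in the nucleus 7 and 7, and the GDI2 circRNA lower in the nucleus (−3.55) was higher in the ribosome fraction (2.83). The value is in line with the hypothesis, but a circRNA abundant in the cytosol could lower both contrasts, which was not tested separately.

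A further hypothesis, also written before, was that circRNAs of short genomic span are relatively nuclear. Span and the nuclear contrast had rho −0.168 and r −0.18 across 528 circRNAs (permutation p = 1.3e-04, adjusted 2.6e-04), and kept calls had median spans of 2138 bases when higher in the nucleus (99) and 5604 when lower (27). The size is small, though in line with the hypothesis. That long spans are relatively ribosomal was not borne out: rho was −0.0824 and r −0.0677 across 725 circRNAs (permutation p = 0.0268, adjusted 0.0357), of the other sign. Span and the exosomal contrast had rho 0.0454 and r 0.0530 (permutation p = 0.412).

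The highest read counts in several tables came from entries that only the caller headed Ciri listed: FGG, a fibrinogen gene, had 17646 cytosolic reads and no other listing, and ALB, the albumin gene (chromosome 4, 73418088 to 73418311), had 17890 cell and 22732 cytoplasmic reads. In exosomes the GRIN2A entry led all others with 114 and 483 reads (32.8 ± 21.8 RPTM), and no other fraction listed it. Of 153 such cytosolic entries of at least 30 reads, 46 (30.1%) were missing from the cytoplasm table, although the cytoplasm holds the cytosol. Of those listed by both callers 13 of 512 (2.54%) were missing (Fisher's exact p = 4.0e-21). Those tables belong to the 2 groups in which the tables appear to have been written, but of cytoplasmic entries 16 of 122 (13.1%) were missing from the cell table of the same group, against 1 of 562 by both callers (Fisher's exact p = 6.5e-12). Of 287 entries of at least 30 reads listed by the caller headed Ciri alone, 77 were in 1 table and 210 in several. Those in 1 table joined 2 genes more often (30 and 30, odds ratio 3.83, Fisher's exact p = 1.4e-05), such as TUBA1B with TUBA1A. Reads shared between near-identical genes are therefore a candidate explanation for part of them. Abundant messenger RNA of secreted liver proteins was left undecided: 4 and 1 lay in such genes (odds ratio 11.5, Fisher's exact p = 0.0194), but FGG and ALB prompted that test, and p was 0.0588 without FGG and 0.0184 without both.

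Exosomal calls were mostly lower than in cells, 401 against 39. For the listing rule and shallow depth in circRNA reads, 0 of 100 simulations of unchanged data gave as many lower calls (at most 98). These alone did not account for them at the 1 common spread simulated for all libraries. Exosomal replicates correlated least (r 0.255), and the simulations tested a median of 771.5 circRNAs against 951, so 98 may be too low a limit. With 200 circRNAs changed, 66 unchanged ones were called, so part of the calls may be false. Scaling by total circRNA reads left 48 lower and 78 higher, but RLE factors left 190 lower and 47 higher, and the implied library totals 841 and 11. In the simulated unchanged data TMM gave a median of 25 lower calls and at most 98, but total circRNA reads gave at most 4. Under the listing rule TMM therefore adds lower calls, though fewer than the 401 observed. RLE factors were not simulated. The scaling factors and a difference cannot be told apart, because the tables do not show which scale is right. Higher calls also outnumbered those of unchanged data (39 against at most 9), so the balance is what stays open, and a biological origin was not tested apart from the preparation, as exosomal RNA alone kept its ribosomal RNA.

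Nuclear calls were mostly lower than in the cytoplasm, 316 against 142, whereas the calls kept in the 4 fits were mostly higher, 114 against 55. In simulated data the rule of the 4 fits kept 94.4% of 36 increases of 3 log2 units and 58.3% of 12 such decreases. For the listing rule and shallow depth in circRNA reads of the nuclear table, 0 of 100 simulations of unchanged data gave as many lower calls (at most 63). These alone did not account for them at the 1 common spread simulated for all libraries. With 200 circRNAs changed, 57 unchanged ones were called, so part of the calls may be false, and the nucleus did not list 277 of the lower ones. Higher calls also outnumbered those of unchanged data (142 against at most 7), so circRNA shares differed in both directions, and a biological origin was not tested apart from the preparation. The balance stays open, as it moved with the fit, from 24 higher and 772 lower with the implied library totals to 116 and 55 with unlisted circRNAs at 1 read and 75 and 24 without nuclear replicate 1.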
